A study of Mus musculus with 27 samples.

How the data were processed

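RNA from 27 mammary tumours (15 of juvenile and 12 of adult hosts) was hybridised to Illumina mouse BeadChips with 45281 probes and up to 6 arrays per chip. Per the file headers, the deposited intensity of each probe is the average over its beads, and its values were found to be neither background-subtracted nor normalized between arrays. Per the file headers, a detection p-value accompanies each intensity. The authors also deposited processed log2 values. Sorted by size, the values of each column matched the mean of the sorted log2 unsubtracted intensities, the quantile-normalized distribution, to within 0.00855. Every array correlated best with its own column (lowest r across probes 0.998) and every column had a median of 6.75. Scale and centring of that table are therefore known from the values. The submitters' processing notes name lumi and limma, and versions and settings are not given in the sources used here.

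Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p and an offset of 16. Probes with a detection p under 0.05 on at least 12 arrays were tested, 19344 in all, of which 16711 had 1 gene symbol, for 10758 genes. On the array 34885 probes had 1 symbol in the platform annotation, 18 had several and 10378 had none; symbols were checked through Entrez identifiers and 0 changed. Genome coordinates are not given because the array files name no genome build. Juvenile minus adult differences were tested with limma's lmFit and eBayes on the log2 scale, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median SE over probes was 0.24 and the median SD within a group 0.60 in juvenile and 0.61 in adult hosts.

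The 34 lists held 515 genes, of which 368 were measured, 99 were detected on too few arrays and 48 had no probe under the names used. A list score was the mean over its members of 1 probe per gene, the detected one with the highest mean. Scores and distances were compared by two-sided permutation tests with 100000 resamples, and the camera test was run with a preset correlation of 0.01 and with an estimated one. With the chip as a block, scores were tested exactly over the 150 placements of host age within chips, which cannot give a p below 0.00667, so after adjustment over 34 lists at least 5 would need that p for any to pass. Within chip 1 there are 15 placements and within chip 3 10, so no p there can fall below 0.0667 or 0.1. The spread used the 1000 most variable probes and leave-one-out group means.

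Named genes were 14 preset genes, the genes past the threshold (at most 12 in each direction), the 6 with the smallest p in a direction with no call, and the 2 or 3 members with the smallest p of a list. This last rule was fixed for each list described, but was applied to part of them, and the other lists are given by their score. For those 6, the rule was read as 1 representative probe per gene after values had been seen, which replaced Spata24 by Tmem135. Eef2 and the single tumours' lists were chosen after their values were seen. The tests, groups, lists and most alternatives were fixed before the data were examined. Alternatives covered the background correction, normalization, filter, chip as block, replicate number as block, array weights, thresholds, other probes and leaving out each chip and tumour.

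The tests were tested on simulated data made from the residuals of all 27 tumours with redrawn labels, in 20 rounds with 200 of 19344 probes changed. For the comparison of host ages, 16.3% of probes changed 1.5-fold, 52.9% changed 2-fold, 93.2% changed 4-fold and 97.9% changed 8-fold were recovered, with a median of 3 false calls among 132.5. Residuals vary slightly less than the tumours do, so recovery is slightly overstated. The redrawn labels, also those for the list scores, ignored the chips, over which host age is unevenly placed. Recovery and false calls under that imbalance were not simulated. List scores shifted by 0, 0.5 and 1 log2 passed an unadjusted 0.05 in 5%, 50.3% and 82.9% of cases, before any adjustment, so a list that did not pass may still differ. No pair of libraries was taken for a duplicate, correlations between tumours running from 0.729 to 0.968 across probes. Figures were drawn with matplotlib 3.10.9.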

Results

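Gene expression was measured on Illumina mouse BeadChips in 27 mammary tumours. The tumours arose from mammary tissue lacking Trp53, the gene of the p53 tumour suppressor, grafted into inguinal fat pads of BALB/c mice whose own ducts had been removed at 3 weeks of age. In 15 tumours the host was 5 weeks old at grafting (juvenile hosts, J1 to J15) and in 12 it was 10 weeks old (adult hosts, A1 to A12). The title of the series speaks of distinct luminal type carcinomas, so the question was how tumours of the 2 host ages differed. Each array detected 17867 to 21050 of 45281 probes, with a median of 18425 in juvenile hosts and 19708 in adult hosts. The number of arrays limits the precision. The p-values compare group differences with the spread between these samples, taken as independent. The labels do not say that each tumour came from its own mouse, and p-values could be too small if tumours shared a mouse. Trp53 and the proliferation marker Mki67 have no probe with that name in the annotation used and were not analysed here.

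Kdm7a, which encodes a histone demethylase, was lower in tumours of juvenile hosts. Its probe ILMN_1231072 averaged 5.11 ± 0.45 (SD, n = 15) in juvenile hosts and 6.07 ± 0.31 (SD, n = 12) in adult hosts, a log2 difference of -0.96 ± 0.16 (SE) with an adjusted p of 0.0438 by limma. In 13 of 15 juvenile-host tumours it lay below the lowest adult-host tumour. The signal was dim: the probe was detected on 9 of 15 juvenile-host and 12 of 12 adult-host arrays, and the brighter Kdm7a probe ILMN_2595814 differed by -0.70 ± 0.19 (SE) with an adjusted p of 0.438. Kdm7a was the single call among 19344 probes tested, and no probe was called higher in juvenile hosts. At an unadjusted p under 0.05 there were 1714 probes, 685 higher and 1029 lower in juvenile hosts, where 967.2 would be expected by chance. Probes are correlated and no range of this count under chance was computed, so no excess is read from it. With single chips left out the count ran from 728 (without chip 1) to 5278 (without chip 5). The call ended when any 1 of 21 of the 27 tumours was left out, and held without J4, J5, J9, J14, A6 or A9.

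Among probes with higher means in juvenile hosts, none passed the threshold. With 1 representative probe per gene, the 6 genes with the smallest p were Aarsd1 (log2 difference 0.58 ± 0.13 SE), Ccdc167 (0.90 ± 0.20), Polr2l (0.67 ± 0.15), Bola1 (0.69 ± 0.17), Elof1 (0.63 ± 0.17) and Tmem135 (0.51 ± 0.14), with adjusted p between 0.347 and 0.438. A probe of Spata24 that was not its brightest, ILMN_3103689, differed by 0.78 ± 0.20 (limma adjusted p = 0.400), with a smaller p than Elof1 and Tmem135. Polr2l encodes a small subunit shared by the nuclear RNA polymerases and Elof1 a transcription elongation factor. The p53 targets Cdkn1a, a cell cycle inhibitor, and Mdm2, the ubiquitin ligase of p53, differed by -0.50 ± 0.28 and 0.02 ± 0.23 (SE). The growth factor receptors Erbb2, Egfr and Igf1r differed by 0.55 ± 0.37, -0.22 ± 0.37 and -0.05 ± 0.31, and the ligand Igf1 by -0.23 ± 0.58. The luminal keratin Krt8 differed by 0.69 ± 0.65 and the basal keratin Krt5 by 0.06 ± 1.09. None of these genes passed the threshold. With 1 probe per gene the smallest adjusted p among the preset ones was 0.582, for Foxa1, and a dimmer Cdkn1a probe, ILMN_2846776, differed by -1.03 ± 0.44 (adjusted p = 0.518).

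The BeadChip was not balanced over host age. Chips 1 and 3 held both groups (2 juvenile-host and 4 adult-host tumours on chip 1, 3 and 2 on chip 3), chips 2 and 4 held juvenile-host tumours only and chip 5 adult-host tumours only. With the chip as a block, limma called 876 probes, 205 higher and 671 lower in juvenile hosts, against 526 within chip 1, 7 within chip 3 and 0 with the chip as a random block (2550 at an unadjusted p under 0.05). Kdm7a differed by -1.16 with the block (adjusted p = 0.0247), -1.04 with the random block (0.243), -1.59 within chip 1 (0.0399) and -0.68 within chip 3 (0.771). With the fixed block Bola1 (0.88, adjusted p = 0.0452) and Elof1 (0.95, adjusted p = 0.0313) also passed the threshold. Erbb2, Egfr and Igf1r differed by 1.71, 1.20 and 0.76 with the block (adjusted p = 0.0589, 0.143 and 0.331), which turned the direction of Egfr and Igf1r. Krt8 and Krt5 differed by 1.80 and 1.89 (adjusted p = 0.300 and 0.544). The only adult-host tumours of chip 3, A5 and A6, had epithelial keratin scores of 5.37 and 5.86, against at least 8.24 in the others on chips 1 and 3. Their Erbb2 was 6.63 and 5.85, against 7.47 to 9.67 in J9 to J11. On chip 1 Krt8 was 13.2 and 12.6 in J1 and J2 and 13.0 to 13.9 in A1 to A4, while Erbb2 was 9.56 and 8.95 against 6.51 to 9.00. These blocked differences therefore cannot be read as host age alone. The 876 calls fell to 0 without J1, 62 without J10, 422 without J2 and 128, 196 and 207 without A1, A2 and A3, and rose to 1687 and 1789 without J9 and J11. Eef2, which encodes a translation elongation factor expressed in all cells, averaged at most 5.16 in J1, J2, J3 and J10 over its 3 probes and at least 11.00 in every other tumour. J1 and J2 are the only juvenile-host tumours of chip 1, so differences within chip 1 cannot separate host age from this library state. The dim Kdm7a probe was lowest of all tumours in J1 and J2, at 4.375 and 4.618. Without the 4 libraries J1, J2, J3 and J10, a choice made after seeing the data, 6 probes were called with the block and 0 without it (1294 at an unadjusted p under 0.05). Kdm7a then differed by -0.83 ± 0.16 (SE) without the block (adjusted p = 0.574) and by -0.65 ± 0.40 with the block (adjusted p = 0.869). That blocked fit compares host ages on chip 3 only, J9 and J11 against A5 and A6. With all tumours the SE of Kdm7a with the block was 0.26, so the smaller comparison can also lower the number of calls.

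**Figure D1:**
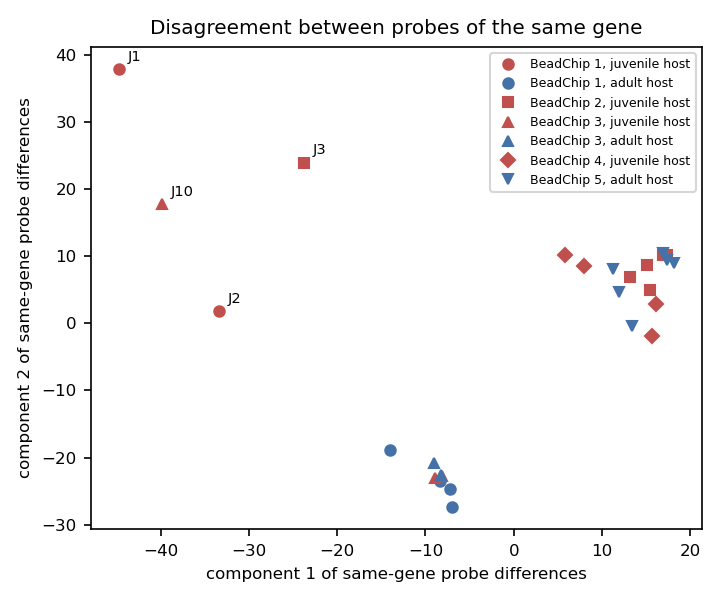
Each point is 1 tumour, placed by the leading pair of components (arbitrary units) of the log2 differences between 2 probes of the same gene, over 1761 genes, with colour for host age and marker for BeadChip. The components hold 41.9% and 34.5% of the variance, and J1, J2, J3 and J10, in which Eef2 was low, are named.

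Esr1, the estrogen receptor, was close to background in most tumours. Its log2 intensity averaged 5.19 ± 0.71 (SD, n = 15) in juvenile hosts and 4.78 ± 0.35 (SD, n = 12) in adult hosts, a difference of 0.41 ± 0.22 (SE) with an unadjusted p of 0.0748 and an adjusted p of 0.594 by limma. It was detected on 9 of 15 and 6 of 12 arrays. Foxa1, a pioneer factor for the estrogen receptor, differed by 1.79 ± 0.92 (SE; detected on 14 of 15 and 9 of 12 arrays), and Pgr, the progesterone receptor, by 0.80 ± 0.42 (SE; 7 of 15 and 3 of 12), though Pgr was on too few arrays for the main test. The luminal regulator Gata3 differed by -0.22 ± 0.62 (SE). Detection of Esr1, Pgr, Foxa1, Greb1, Gata3 and Erbb2 did not differ past the threshold between the host ages (two-sided Fisher's exact test, smallest adjusted p 0.849 over 6 genes). With the chip as a block Esr1 differed by 0.28, and within chips 1 and 3 by 0.15 and 0.43.

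**Figure D2:**
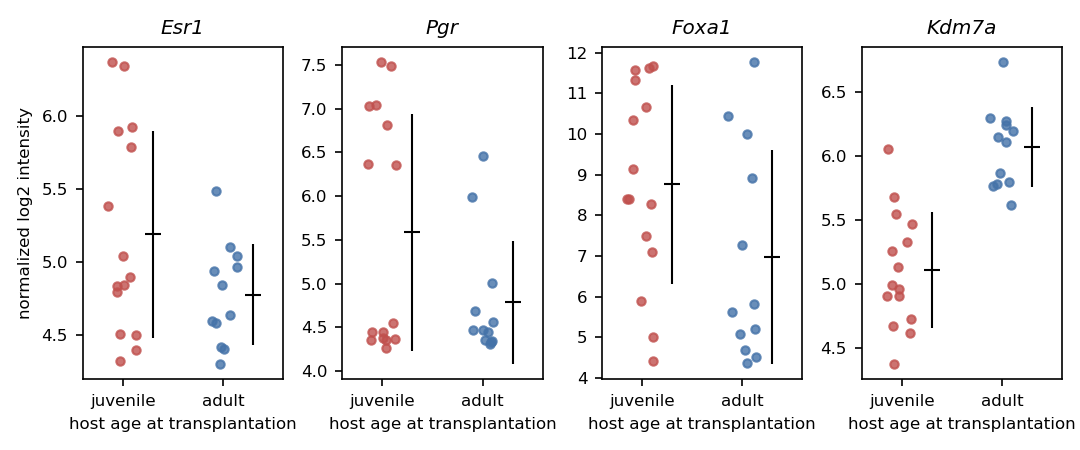
Normalized log2 intensity of Esr1, Pgr, Foxa1 and Kdm7a in each tumour (points), by host age at transplantation, with the mean and SD beside the points. The groups overlap for each gene, and for Kdm7a 13 of 15 juvenile-host tumours lie below the lowest adult-host tumour.

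Gene groups fixed before the data were examined were compared through the mean log2 intensity of their measured members in each tumour. No list of 34 passed the two-sided permutation test after Benjamini-Hochberg adjustment, the smallest adjusted p being 0.354, and no list member other than those named below passed a threshold. Of the 4 lists with an unadjusted p under 0.05, all had higher scores in juvenile hosts, and 0 lists had such a p when all detected probes of a gene were averaged. The estrogen responsive list differed by 0.39 ± 0.17 (SE; p = 0.0289), with 10 of its 12 measured members higher, among them the growth factor binding protein Igfbp5 (0.91 ± 0.47), the secreted glycoprotein Stc2 (1.57 ± 0.87) and the chemokine Cxcl12 (1.02 ± 0.59). S phase and replication genes differed by 0.30 ± 0.14 (p = 0.0382), with 14 of 16 higher. Chaf1b, a chromatin assembly factor subunit, differed by 0.77 ± 0.25 and Gins2, a helicase component, by 0.61 ± 0.20, and these 2 members passed when p was adjusted over the list alone (0.0422 each) but not over all genes (0.490 each). Without the 4 low-Eef2 libraries they differed by 0.84 and 0.71 (0.0607 and 0.0581 over the list), and with the chip as a block by 1.02 and 0.08 (0.0489 and 0.918 over all genes), or 0.77 and 0.05 with both (0.888 and 0.999). Oxidative phosphorylation genes differed by 0.16 ± 0.08 (p = 0.0416; 19 of 23 higher) and cytosolic ribosomal protein genes by 0.13 ± 0.06 (p = 0.0221; 11 of 12 higher), with Ndufs7 at 0.29 ± 0.13, Atp5o at 0.29 ± 0.13, Rpl19 at 0.39 ± 0.15 and Rpl32 at 0.40 ± 0.19.

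Epithelial and luminal groups had higher mean scores in juvenile hosts without passing the test. The epithelial keratin and junction list differed by 0.77 ± 0.62 (SE; 14 of 14 members higher), with the epithelial transcription factor Elf3 at 1.04 ± 0.54, Krt7 at 1.39 ± 0.73 and Krt19 at 1.79 ± 0.97. Luminal progenitor genes differed by 0.74 ± 0.47 (10 of 10 higher), with the aldehyde dehydrogenase Aldh1a3 at 1.10 ± 0.39, the lipocalin Lcn2 at 1.00 ± 0.59 and the iron binding protein Ltf at 1.62 ± 0.96. Mature luminal and hormone receptor genes differed by 0.69 ± 0.50 (8 of 9 higher), basal and myoepithelial genes by 0.62 ± 0.66 (10 of 10 higher; Tagln 0.53 ± 0.35, Cdh3 0.83 ± 0.61) and milk genes by 0.22 ± 0.52 (6 of 10 higher; Xdh -0.76 ± 0.37, Csn3 1.05 ± 0.83). Mesenchymal transition genes differed by -0.39 ± 0.34 (11 of 12 lower; Mmp2 -0.85 ± 0.44, Prrx1 -0.59 ± 0.38) and collagen matrix genes by -0.34 ± 0.36 (11 of 13 lower; Col6a1 -0.91 ± 0.51, Col5a1 -0.54 ± 0.39). Collagen genes differed by 0.05 with the chip as a block and by 0.66 within chip 1. Single tumours moved these values. The milk difference was 0.05 without J6 and 0.54 without A9. The epithelial keratin difference was 0.42 without A5, 0.46 without A6 and 1.08 without J4. The basal one was 0.39 without A6 and 0.87 without A7. The mesenchymal one was -0.26 without A1, -0.19 without A6 and -0.52 without A11, and the collagen one -0.19 without A6 and -0.54 without A11. The camera test with a preset correlation between genes called 8 lists: epithelial keratin, luminal progenitor, S phase, oxidative phosphorylation and blood genes higher, and mesenchymal transition, collagen matrix and cholesterol biosynthesis genes lower. With an estimated correlation it called 0 of 34, the smallest adjusted p being 0.692.

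No immune or stromal list passed the test. T and NK cell genes differed by 0.26 ± 0.19 (SE), B and plasma cell genes by 0.21 ± 0.25, interferon response genes by 0.30 ± 0.25 (17 of 18 members higher), macrophage genes by -0.23 ± 0.24 (Lyz2 -1.27 ± 0.54, C1qa -0.89 ± 0.39), neutrophil genes by -0.17 ± 0.47 and MHC class II genes by -0.25 ± 0.28. Lymph node genes differed by 0.03 ± 0.30, endothelial genes by -0.05 ± 0.43, Schwann cell genes by 0.11 ± 0.27, blood genes by 0.80 ± 0.47 (4 of 4 members higher), skeletal muscle genes by 0.48 ± 0.56 and squamous keratin genes by -0.05 ± 0.54. Leaving out 1 tumour turned some of these signs. Lymph node genes then stood at -0.18 without J4, endothelial genes at 0.27 without A5 and squamous keratin genes at 0.33 without A7. Adipocyte genes differed by 0.27 ± 0.28, with the hormone Lep at 0.81 ± 0.26 (adjusted p = 0.0430 over the list alone, 0.490 over all genes), which was 0.34 with the chip as a block. The lipid droplet gene Plin4 differed by 0.81 ± 0.45. With the chip as a block Schwann cell genes differed by 1.18 (exact p = 0.0133, the smallest of all lists), T and NK cell genes by 0.57 (exact p = 0.0467), squamous keratin genes by 1.20, endothelial genes by -0.99 and blood genes by 0.05. Schwann cell genes (1 of 4 members higher over all tumours) differed by 0.30 within chip 1 and 2.16 within chip 3. On chip 3 the adult-host side is A5 and A6, with Schwann cell scores of 6.407 and 7.045. Endothelial genes differed by -0.17 within chip 1 and -1.89 within chip 3, with A5 at 11.7. T and NK cell scores were 6.90 to 7.62 in the low-Eef2 J1, J2 and J10 and 6.07 to 6.68 in the others on chips 1 and 3.

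No growth or stress pathway list passed the test. The p53 target list differed by -0.03 ± 0.08 (SE), mitotic genes by 0.19 ± 0.20, the insulin-like growth factor axis by -0.07 ± 0.19 (Insr -0.77 ± 0.25, Igfbp3 -1.54 ± 0.78), hypoxia genes by 0.0002 ± 0.24, Wnt targets by -0.17 ± 0.24, Notch genes by 0.01 ± 0.27 and TGF-beta genes by -0.08 ± 0.15. Immediate early genes differed by 0.20 ± 0.16 and cholesterol biosynthesis genes by -0.24 ± 0.14 (12 of 12 members lower; Cyp51 -0.70 ± 0.25, Nsdhl -0.72 ± 0.39). The unfolded protein response list differed by -0.08 ± 0.14, with 9 of 14 members higher (Hspa5 0.17 ± 0.15) while its chaperone Calr stood at -1.69 ± 0.50 (adjusted p = 0.0305 over the list alone, 0.489 over all genes). Calr lay at 6.43 to 8.85 in the 4 low-Eef2 libraries and differed by -0.99 ± 0.41 without them (0.349 over the list), by -3.13 with the chip as a block (adjusted p = 0.0294 over all genes) and by -0.30 with both (0.792 over the list). With the chip as a block no list passed, but a lone list could not have (smallest possible adjusted p 0.227). The block turned the sign of 8 lists (collagen matrix, hypoxia, MHC class II, adipocyte, squamous keratin, Wnt, Notch and immediate early genes), and 18 kept 1 sign over all tumours, with the block and within chips 1 and 3. These settings share tumours, and the juvenile-host side of chip 1 is J1 and J2, both low-Eef2 libraries. The shared sign is therefore no independent evidence on host age. Epithelial keratin genes differed by 2.31 with the block, 0.15 within chip 1 and 4.72 within chip 3, where the only adult-host tumours are the keratin-poor A5 and A6 (scores 5.37 and 5.86). In that order, estrogen responsive genes differed by 0.46, 0.32 and 0.63, and S phase genes by 0.37, 0.49 and 0.24.

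**Figure D3:**
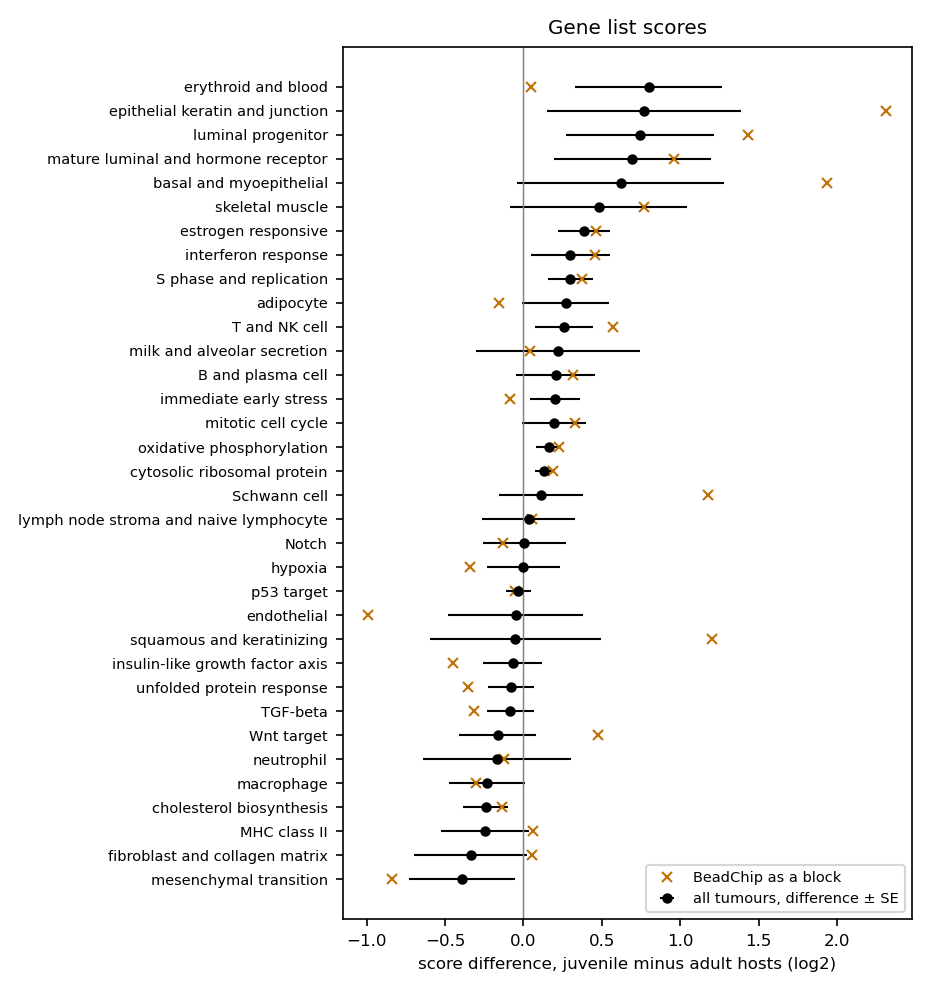
Difference in score (log2, juvenile minus adult hosts) of each of 34 gene lists, with bars for the SE over 27 tumours and crosses for the value with the BeadChip as a block. The estrogen responsive list lies at 0.39 ± 0.17, and no list passed the adjusted threshold.

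The spread between tumours did not differ past the threshold between the host ages. Over the 1000 most variable probes, the mean distance of a tumour from the mean of its own group was 56.6 ± 11.3 (SD, n = 15) in juvenile hosts and 58.8 ± 10.0 (SD, n = 12) in adult hosts, in log2 units. The difference of -2.17 was within the spread (two-sided permutation test, p = 0.612). The epithelial keratin score ran from 5.37 to 11.0, the mature luminal score from 6.01 to 10.2 and the basal score from 5.84 to 11.5 across the tumours. Foxa1 was over 10 in J3, J7, J10, J12, J13 and J14 and in A4, A7 and A8.

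**Figure D4:**
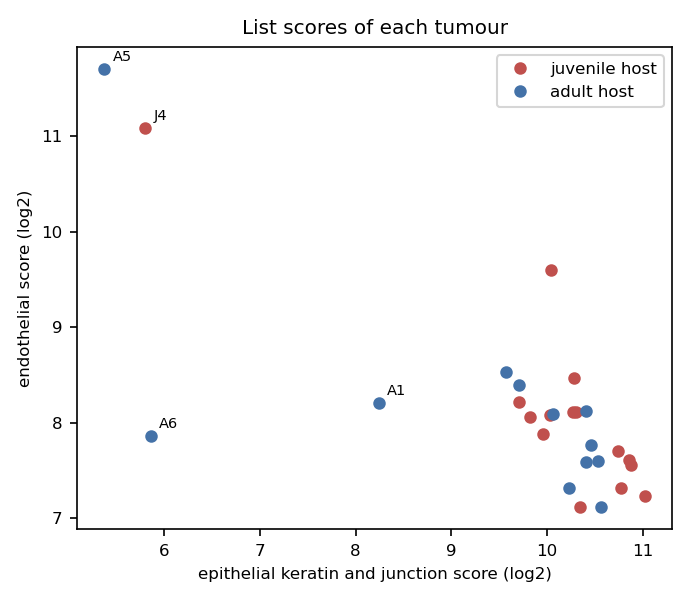
Each point is 1 tumour, placed by its epithelial keratin and junction score and its endothelial score (mean log2 intensity of the list members), coloured by host age. J4 and A5 have endothelial scores of 11.1 and 11.7 against at most 9.60 in the others.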

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

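The alternatives on the 4 libraries with low Eef2, on same-gene probe components and on the replicate block of list scores were added after seeing the data. Against 1 probe called, limma gave 0 with the authors' processed values, quantile normalization without background correction, trend and robust variance, a detection p under 0.01 on every array (both the p and the number of arrays were changed), the chip as a random block or any of chips 1 to 4 left out, where 662 to 2550 probes had an unadjusted p under 0.05. It gave 2 with median scaling and with array weights, 876 with the chip as a fixed block, 526 within chip 1, 7 within chip 3 and 1543 without chip 5, and 0 to 2 with single tumours left out. Without chip 5, all remaining adult-host tumours lie on chips 1 and 3. With probe components as covariates it gave 0 (819 unadjusted), without the 4 libraries 0, also without chips 1 and 3 0 (1033 unadjusted), and without the 4 libraries with the chip as a block 6. The other causes were not tested. The replicate block, on numbers that do not pair the samples (2 of 12 correlations over 0.1, none best with its own number), gave 0 probes (1315 unadjusted) and 0 lists.

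Kdm7a kept its sign in 20 settings, at -1.59 to -0.31, and lost its call in 14 of them. The 16 other named genes in the test passed in 7 of 764 alternatives, all with the chip as a fixed block or without chip 5. Esr1 stayed positive at 0.13 to 0.61 in 19 settings and at 0.33 to 0.48 with single tumours left out, and was -0.024 on the probe ILMN_1221362. The spread difference of -2.17 became 1.69 with the chip as a block, 1.12 without chip 3, 1.18 without chip 4 and 0.0136 as 1 minus the Pearson correlation, and ran from -4.41 to -0.220 with single tumours left out; the cause was not tested. It moved the other way to -9.79 with probe components as covariates (p = 0.0719), -8.71 without chip 1, -7.53 without chip 5 and -5.89 without the 4 libraries, and passed the threshold in no setting. No list passed in any permutation setting (with the chip as a fixed block fewer than 5 lists could not have), and against 4 lists with an unadjusted p under 0.05 there were 0 with all detected probes of a gene averaged, 1 without the 4 libraries or without chip 1, 2 or 3, and 8 without chip 5; camera with a preset correlation called 8. All 1394 alternatives of single lists stayed on the same side of the threshold. Signs moved more: 10 lists changed sign with probe components as covariates and 9 without the 4 libraries and chips 1 and 3. Of those 9, 1 had an unadjusted permutation p under 0.05 in that setting or in the main test. In every other permutation setting at most 8 lists changed sign. A single tumour left out changed 23 of the 34 list differences by more than 1.5 times, up or down. For differences near 0, such as hypoxia (0.0002) and Notch genes (0.005), any small change gives a large ratio, so the count overstates how far single tumours moved them. Signal over background limits Esr1, Pgr and the dim Kdm7a probe ILMN_1231072, which lie close to the detection limit.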

Other observations

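Single tumours differed in cell type genes that the comparison of host ages does not describe, chosen after their values were seen. A7 had the highest squamous and keratinizing score (10.8), A9 the highest milk score (10.8), J11 the highest neutrophil score (11.0) and A6 the highest mesenchymal transition score (10.7) with an epithelial score of 5.86. Skeletal muscle scores were 10.4 in J4, 9.81 in J1, 9.16 in A3 and 8.31 in A6, against a median of 5.62 in tumours other than J4 and A5. The lymph node score was 8.68 in J4.

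All tests below were chosen after the results were seen, except that the bound for the 876 probes in other tumours was written before its value; the 4 libraries left out there were picked from the data and its spread was changed after a first run. Of 100 splits of the 27 tumours into 15 and 12, the real one included, 2 gave as many calls as the real one (1 probe, highest other 1). These splits ignore the chips, and with the chip as a random block the adjusted p of Kdm7a was 0.243, so chance is not excluded. Of 100 splits that kept each chip's numbers, the real one included, 3 gave at least the 876 calls of the chip-blocked fit, and the highest other gave 936. The count depends on single libraries of both host ages (0 calls without J1, 62 without J10, 128 without A1, 1789 without J11), so a chance placement of such libraries is not excluded.

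The 876 chip-blocked calls were weighed first. A host age effect shared by all tumours would shift these probes elsewhere too, but in 9 juvenile-host and 6 adult-host tumours outside chips 1 and 3 and the 4 low-Eef2 libraries the median ratio of their difference to the blocked one was -0.0311 (SD 0.0397 over 5005 placements of the labels), with 42.5% in the same direction. These 9 tumours lie on chips 2 and 4 and the 6 on chip 5, so the ratio is confounded with the chip, which the placements ignore, and a shared host age effect stays open. A candidate explanation is the altered probe response of J1, J2 and J10: without these 3, 6 calls remained. The rule set for that test asked for fewer calls than after leaving out any other 3 juvenile-host tumours of the chips, and other sets left as few as 0, so it was not met; the rule was a poor one, since each other set holds at least 1 of the 3 libraries. Sets with 2 of them left 0 to 192 calls and sets with 1 left 1382 to 3159. Leaving out J1 and J2 also leaves chip 1 without a juvenile-host tumour, which takes it out of the blocked comparison. With J9 or J11 as the third, such sets left 2 and 6 calls. With J2 kept on chip 1, leaving out J1, J9 and J10 or J1, J10 and J11 left 0 calls. With J1 kept there, leaving out J2 and J10 with J9 or J11 left 192 and 10. Leaving out J9, J10 and J11, all juvenile-host tumours of chip 3, left 1773. Loss of a chip from the comparison is therefore argued against as the only cause of the fall. These sets share libraries and the rule was not met, so the altered probe response stays open as an explanation.

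Sets of chips differed within host ages: 3960 probes differed between the 6 adult-host tumours on chips 1 and 3 and the 6 on chip 5. The labels give the chip but no array run, and chips 1 and 3 were grouped because they held both host ages. A probe response that differs between these sets of chips would lower the correlation of the differences of 2 probes of the same gene. Across 1761 genes, which are not independent replicates, this correlation was 0.417 for these chips. In 20 random splits of other tumours it was at least 0.738, so the low value is what such a response predicts. For the 4 low-Eef2 libraries it was 0.322 against juvenile-host tumours of other chips (random splits at least 0.765). A difference between whole chips cannot by itself account for these 4. Against the other libraries of their own chips the correlation was 0.417 (draws from other chips at least 0.721), as a probe response of single libraries predicts. A chip difference, whose rule the 0.322 met, can be present as well and is not excluded. None of the 4 libraries lay below the lowest other array in median intensity or in detected probes. On chips 1 and 3, however, J1, J2 and J10 had 17959, 19099 and 18425 detected probes and every other library at least 19852. J3, at 18644, lay inside the range of the others on chip 2 (18274 to 18790). In median intensity J1 and J10 (111.5 and 111.8) lay above every other library of chips 1 and 3, which reached at most 110.2. J2, at 102.7, lay inside the range of the others. These values include background, and the 5th percentile was also highest on these chips in J1 and J10 (99.1 and 98.5). Low raw intensity was thus not seen in J1 and J10, but low signal over background of J1, J2 and J10 stays open. Without the 4 libraries, 2203 probes differed between J9 and J11, both on chip 3, and the 9 other juvenile-host tumours, on chips 2 and 4. Component 1 of the same-gene probe differences was -8.92 in J9 and -8.16 in J11, and -14.0 to -6.95 in A1 to A6. It was at least 5.82 in all libraries of chips 2, 4 and 5 but J3, so this probe response was seen at both host ages. Tumour types unevenly placed on the chips remain open as a further cause for the adult-host tumours. Their basal list differed by 1.92 times its standard error between the chips. No biological explanation for the 4 libraries was tested.

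J4 and A5, 1 tumour of each host age, had endothelial scores of 11.1 and 11.7 (others 7.12 to 9.60), with Pecam1 at 12.0 and 13.5 and Cdh5 at 11.5 and 12.3. Host vessels mixed into a keratin-rich tumour are argued against by Krt8, which lay at least 6.03 below the median of the others in both (a difference of -6.03 in A5). Host tissue without tumour cannot be told apart from a tumour here: the lower p53 target score was -0.311 SDs from the median of the others, inside their range, the mitotic scores of 8.07 in A5 and 8.18 in J4 were under the median of 8.90 but also inside the range of the others (from 7.86), and J4 also held muscle and adipocyte genes (scores 10.4 and 9.07). A hypothesis that these are vascular tumours may be followed up by histology. No biological explanation from the design was tested, since each host age holds 1 of them.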
